A study of Drosophila melanogaster with 2 samples.

How the data were processed

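Binding of Vsx2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole wandering larvae of Drosophila melanogaster. Vsx2 is a homeodomain transcription factor. The transgenic line carried Vsx2 with a GFP tag at its C-terminus, and the tagged protein was precipitated with an antibody against GFP, per the labels. Males and females were pooled. There were 2 biological replicates, in 1 group. Chromatin was sonicated, and the fragments were 200 to 300 bp long in replicate 1 and 225 to 300 bp long in replicate 2, per the labels.

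The values used were peak lists deposited by the authors in the narrowPeak format, on the genome builds dm6 and dm3. Each build had 4 lists. A relaxed list of 30000 peaks, which holds peaks together with background as input for the irreproducible discovery rate (IDR) procedure, was given for each replicate and for the pooled reads of both. The fourth list held the peaks past the IDR threshold. Per the labels' accompanying notes on the deposited peak lists, a control library entered the calls. The signal value of a peak is the strength that the authors' peak caller gave it, and it was not scaled between lists. The −log10 q-value was likewise deposited by the authors. The column for p-values held the same placeholder in each row and was not used. The aligner, the peak caller, their versions and the IDR threshold are not stated in the labels. Read counts and sequencing depth were not analysed here, so the depth of each replicate is unknown here and intervals cover counting error in the number of peaks alone. The dm6 IDR list was identical to the 2824 peaks of highest signal value in the pooled relaxed list, and the dm3 IDR list to the 2566 of highest signal value in its own pooled list.

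All gene and sequence results used the dm6 lists with the Release 6 genome sequence and the Ensembl release 115 annotation of the same assembly, with transposable elements left out. Each dm6 peak lay within the length of its chromosome arm. The dm3 lists served for replicate overlap and for peak density alone, and no coordinate was converted between builds. Positions are 1-based dm6 positions.

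A promoter peak had its summit within 500 bp of an annotated transcription start, and other peaks are called distal. Distal summits were classed by the annotation in the order coding exon, 5′ UTR, 3′ UTR, non-coding exon, intron and intergenic. Shares carry 95% Wilson intervals. Promoter shares were compared with 1000 circular shifts of the summits within each arm (two-sided permutation test) and with a background set, the 2824 weakest pooled relaxed peaks more than 1000 bp from any IDR peak. Replicates were compared through the 2824 strongest relaxed peaks of each, and summits within 100 bp counted as shared. The overlap was set against 1000 circular shifts of the replicate 2 summits (one-sided permutation test). The signal of promoter and distal peaks was compared by the difference of the median log2 signal values with 100000 resamples.

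Each summit was assigned to the protein-coding gene with the nearest transcription start, and to each of the genes where several share that start (38 IDR peaks). For 21 gene lists, the members with at least 1 IDR peak were counted and compared with 10000 random lists matched on decile of the distance along the genome over which a gene's starts are the nearest (two-sided permutation test). P-values were adjusted by the Benjamini-Hochberg method over the 21 lists. All 408 distinct genes were found, 7 list entries through a synonym. Sequence was read 100 bp to each side of the summit and in windows of equal size 1000 bp away on both sides. For 19 motifs, the share of peaks with a match was compared between summit and flanks by a sign-flip permutation test with 100000 resamples, adjusted over the 19 motifs. All 2080 6-mers, each counted together with its reverse complement, were compared between the summit and 1 flank by the exact McNemar test, and called at an adjusted p below 0.05 and a fold of at least 1.5. Peaks were split by strength into 5 parts of near equal size. Motif shares were compared by Fisher's exact test between the strongest and the weakest part, and between all promoter and all distal peaks. The gene lists, the motifs, the tests and the rule for naming genes were chosen before the data were examined.

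Named are Vsx2 and Vsx1, the genes nearest to the 20 strongest IDR peaks, up to 4 members of each gene list with the strongest IDR peaks, and the 10 6-mers of smallest p. Alternatives were single replicates in place of the IDR list, the stronger 1412 IDR peaks, X left out, other promoter, motif and flank distances, other matching rules and other random sets, with their effects in the closing section.

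The tests were tried on simulated data. Of 10 6-mers written into 10% of 2823 windows far from summits, 10 were recovered. At 5% of windows 7 were recovered past the fold threshold, and at 2% of windows 1 was. With nothing written in, no 6-mer was called. Both sets of windows lay away from summits, so this run does not test calls that come from a difference in base composition between summits and flanks. In 20 runs with randomly shifted summits, 0 of 420 gene lists were called. The shifts remove the concentration of peaks at promoters, so these runs do not show how often lists are called for promoter-rich peaks. When 80% of the members of 4 lists per run were given a peak, 77 of 80 such lists were called. The promoter test called 3 of 40 shifted sets. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.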

Results

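Peaks bound by Vsx2-eGFP were mapped by ChIP-seq in whole wandering larvae, in 2 biological replicates of a single group. Vsx2 is a paired-class homeodomain factor related to vertebrate CHX10, and it is expressed with its neighbour Vsx1 in the central part of the medulla primordium in the larval optic lobe. The IDR list on dm6 held 2824 peaks with a median width of 216 bp. Their signal values, in the units of the authors' peak caller, ran from 79.7 to 6882 with a median of 120.01. The nearest transcription starts belonged to 1809 of 13945 protein-coding genes, or 13.0%, and 254 genes had 3 or more peaks.

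The first question was how far the replicates gave the same peaks. Of the 2824 strongest peaks of replicate 1, 1431 had a summit within 100 bp of one of the 2824 strongest of replicate 2, which is 50.7% (95% Wilson interval 48.8 to 52.5%). Shifted summits shared 0.446% on average and at most 0.921%, and the one-sided permutation p of 0.0010 was the smallest the shifts can give. Across the shared peaks, which are not independent replicates, log2 signal values had a Pearson r of 0.82 and a Spearman rho of 0.65. Of the 2824 IDR peaks, 1430 lay among the strongest of both replicates, 587 among those of replicate 1 alone, 593 among those of replicate 2 alone and 214 among those of neither. The peak of highest signal, at the promoter of CG3253, ranked 1 in each replicate.

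**Figure D1:**
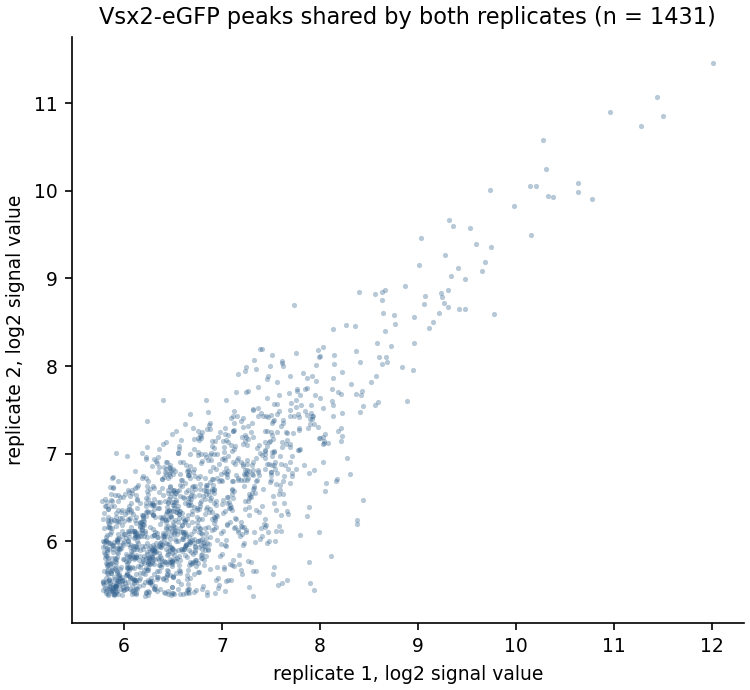
Each point is one of the 1431 peaks shared by the replicates among the 2824 strongest of each, with the log2 signal value of replicate 1 on the horizontal and of replicate 2 on the vertical axis. The strongest peaks lie close to a common line, and the weaker ones scatter widely, with a Spearman rho of 0.65 over all points.

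Vsx2-eGFP peaks were concentrated at promoters and were nearly absent from coding exons outside them. Promoters held 1422 summits, or 50.4% (95% Wilson interval 48.5 to 52.2%), against 14.2% of shifted summits and 13.3% of the weakest relaxed peaks. Introns outside promoters held 857 summits (30.3%) and intergenic sequence 438 (15.5%), both fewer than among shifted summits, where they held 38.3% and 27.1%. Coding exons held 12 summits (0.425%) against 14.4% of shifted ones, and 5′ UTRs beyond the promoter window held 41 (1.45%) against 0.622%. The 3′ UTRs held 29 summits (1.03%) against 4.53%. Each of these departures had a two-sided permutation p of 0.0020, the smallest the shifts can give, and an adjusted p of 0.0023, and non-coding exons did not depart (0.885% against 0.857%, adjusted permutation p = 0.92). Promoter peaks were also stronger than distal peaks, with median signal values of 128.8 and 112.6, a difference of 0.19 on the log2 scale (two-sided permutation p = 2.0e-05, the smallest the resampling can give). The promoter share was 55.4% among the strongest peaks of replicate 1 and 45.3% among those of replicate 2.

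**Figure D2:**
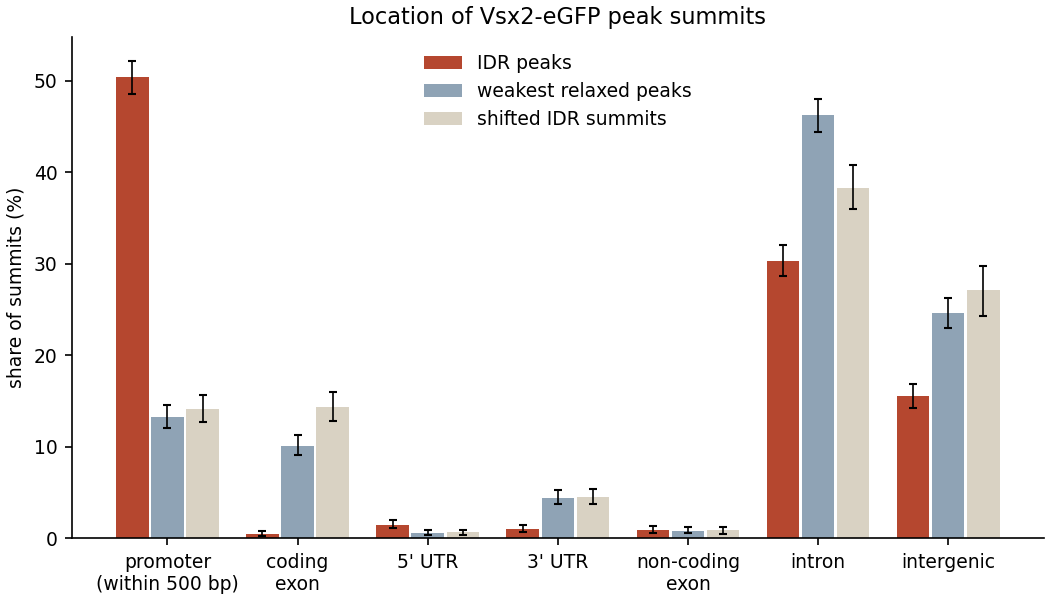
Bars give the share of summits in percent by location for the IDR peaks, the weakest relaxed peaks and the shifted IDR summits, with 95% Wilson intervals for the first pair of sets and the middle 95% of 1000 shifts for the last. IDR summits reach 50.4% at promoters, where shifted summits reach 14.2%, and 0.425% in coding exons, where shifted summits reach 14.4%.

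The strongest peaks lay mostly at promoters. Of the 20 strongest IDR peaks, 19 were promoter peaks, and all 20 together fell near 19 genes. The strongest lay on 2R from 24114213 to 24114508, with its summit 49 bp upstream of CG3253 and a signal value of 6882. It was followed by peaks at Coq2 (signal value 4791), an enzyme of ubiquinone synthesis, at Mic26-27 (4713), a component of the mitochondrial MICOS complex, at CG12299 (4169) and at Smg5 (3798), a factor of nonsense-mediated mRNA decay. The peak of rank 6 (signal value 2755) was the exception. It lay in intergenic sequence with its summit 1051 bp upstream of Der-1, a gene of endoplasmic reticulum protein degradation. The remaining promoters were those of gus, with a pair of peaks at separate starts (signal values 2713 and 1851), CG8950, DUBAI, CG2765, CG8617, Gnpat, Su(z)12, a subunit of Polycomb repressive complex, eIF2Balpha, a translation initiation factor subunit, CG5515, trbd, CG8500, rtet and mbc, with signal values from 2581 at CG8950 down to 1441 at mbc. Among these 20 peaks, TAATTAG occurred within 100 bp of the summit at CG2765 and mbc alone, and the shorter TAATTA also at rtet. The replicates ranked these peaks alike, with ranks from 1 to 23 in each.

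The tagged gene itself carried peaks. Vsx2 (FBgn0263512) lies on the minus strand of X from 5528927 to 5560183, and Vsx1 (FBgn0263511) on the plus strand from 5594255 to 5612865. The strongest IDR peak assigned to Vsx2 lay from 5560582 to 5560797, with its summit 507 bp upstream of the transcription start, a signal value of 194.4 and rank 582. It ranked 500 in replicate 1 and 284 in replicate 2. A peak with its summit 3456 bp upstream of Vsx2 (rank 875, signal value 156.4) contained TAATTAG. Vsx2 had further IDR peaks 13480 bp upstream (rank 2504) and in its intron, 10620 bp downstream of the start (rank 2596). The first of these ranked 5832 in replicate 1 and the second 3470 in replicate 2, each outside the 2824 strongest there. The single IDR peak assigned to Vsx1, 14677 bp upstream of its start in the sequence between the genes, had rank 2089 and a signal value of 95.3. It ranked 1170 in replicate 2 and 4348 in replicate 1, outside the 2824 strongest there. Beyond the 3′ end of Vsx2, the promoter of CG12730 held a stronger peak (summit at 5517184, rank 58, signal value 694.9) that ranked 54 in replicate 1 and had no summit within 100 bp in the replicate 2 list. CG12730 was named after its value was seen.

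**Figure D3:**
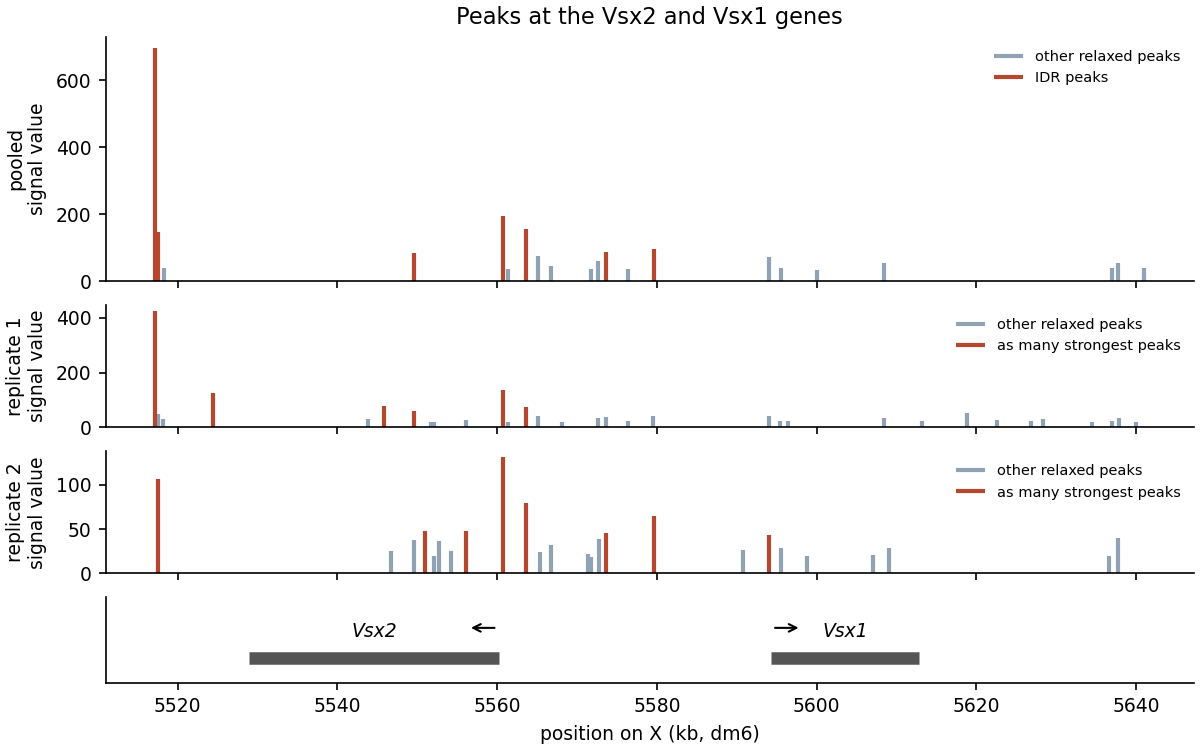
Peaks around Vsx2 and Vsx1 on X (dm6, horizontal axis in kb), drawn at their summits with heights equal to the signal value in the pooled list and in each replicate. Red lines are IDR peaks, or in the replicates the 2824 strongest, blue lines are other relaxed peaks, and bars with arrows are the genes with their direction of transcription. Peaks 507 and 3456 bp upstream of Vsx2 are among the strongest 2824 in both replicates, where they rank 500 and 1754 in replicate 1 and 284 and 801 in replicate 2. The tallest line, at 5517184, has a counterpart within 100 bp in replicate 1 alone.

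Genes of optic lobe patterning, of retinal determination and of imaginal disc signalling were occupied far more often than matched random genes. The match covered the distance over which a gene's starts are nearest, but not open chromatin or promoter activity. An excess is thus not shown to be particular to the tagged factor. In the optic lobe neuroepithelium list, 10 of 12 genes had at least 1 IDR peak against 3.91 in random lists (adjusted permutation p = 0.0025), led by bi, a T-box gene (signal value 269.2, in an intron), Vsx2, hth (176.6) and wg (159.6). These 10 include the tagged gene Vsx2 and its neighbour Vsx1, and genes such as bi and wg that the disc list also holds. The list was not tested without them. Some genes belong to several lists, among them most of the retinal determination genes. The list of temporal factors, which succeed each other in optic lobe neuroblasts, had 14 of 17 genes occupied against 5.13 (permutation p = 0.00020, the smallest the random lists can give, adjusted p = 0.0014). Its strongest peaks were at ey, the fly Pax6 gene (417.6), opa (309.8), klu (304.6) and B-H2 (257.1). Retinal determination genes were occupied in 10 of 11 cases against 3.47 (adjusted permutation p = 0.0025), led by ey, eyg (395.7), so (348.9) and tsh (270.9). Of the imaginal disc signalling genes, 21 of 22 had a peak against 6.82 (adjusted permutation p = 0.0014), led by nub (410.2, with TAATTAG at the summit), sd (339.5), bi and brk (268.4).

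Homeobox genes and the Notch pathway were the other occupied groups. In the list of other homeobox genes, which leaves out Hox genes and some homeobox genes of the other lists, 35 of 62 had a peak against 15.6 (adjusted permutation p = 0.0014). The strongest were at caup, an Iroquois gene (467.3, intronic and with TAATTAG), Awh (434.4), eyg and C15 (385.6). Of the Notch pathway genes, 10 of 17 had a peak against 3.46 (adjusted permutation p = 0.0049), with the strongest at kuz, the protease that cleaves Notch (465.1, intronic and with TAATTAG), mam (387.0), fng (269.9) and E(spl)m3-HLH (170.5). These 6 of the 21 lists passed an adjusted p of 0.05 in the permutation tests. They share genes with each other, so they are not 6 independent results. With the stronger 1412 IDR peaks alone, 3 lists passed, and the neuroepithelium (6 of 12 genes), temporal factor (8 of 17) and Notch (5 of 17) lists were no longer among them. The neuroepithelium list also fell short when summits had to lie within the gene or 1000 bp upstream (8 of 12) or within 500 bp of a start (5 of 12), and the Notch and retinal determination lists did so when promoter peaks were left out (5 genes each).

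Another 4 lists did not depart from random lists after adjustment. Hox genes had 6 of 8 members occupied against 2.84 (adjusted permutation p = 0.11), with peaks at lab (186.9), abd-A (156.7), Dfd (142.3) and Abd-B (121.7). Ecdysone response genes had 10 of 16 against 5.22 (adjusted permutation p = 0.071), among them Eip74EF (299.95) and Eip75B (246.2), targets of the moulting hormone, Blimp-1 (204.1) and E23 (199.1). This list passed in replicate 1 alone with 11 of 16 genes (adjusted permutation p = 0.010), and with peaks on X or the strongest 282 peaks left out (0.044 in both). Medulla neuron identity factors had 8 of 18 against 5.74, with peaks at tup (295.8), vvl (232.5), Lim3 (222.1) and ap (212.9). Neuroblast and proneural genes had 9 of 22 against 5.91, with peaks at nub, brat (328.7), numb (149.95) and ato (135.8). For these last lists the adjusted permutation p was 0.51 and 0.38, and both passed when a summit had to lie within 500 bp of a start of the gene (0.018 and 0.0049).

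The 11 lists of differentiated cell types, heat shock genes and ribosomal protein genes did not depart from random lists after adjustment either. None of 18 phototransduction genes had an IDR peak against 3.32 in random lists (permutation p = 0.040, adjusted 0.10). None of 12 fat body genes and none of 9 salivary gland glue genes had one, where random lists had 1.65 and 0.337. Pan-neuronal genes had 2 of 14 occupied (futsch and brp) against 4.28, neurotransmitter genes 1 of 14 (Hdc), or 0.401 times the mean of random lists, and glial genes 3 of 13 (pnt, gcm and Mdr65) against 2.52. Muscle genes had 4 of 18 (Zasp52, Mef2, Tm1 and Act88F) against 4.38, haemocyte genes 2 of 11 (ush and crq) against 2.20, and midgut genes 4 of 15 (nub, thetaTry, esg and Mal-A1) against 1.55. Heat shock genes had 2 of 15 (Hsp26 and Hsc70-4) against 1.47, and the cytoplasmic ribosomal protein genes had 10 of 88, led by RpL23A, RpL7, RpL41 and RpL38, against 7.28. In these 11 lists the adjusted permutation p ranged from 0.10 to 1. The heat shock list passed in replicate 1 alone with 7 of 15 genes (adjusted permutation p = 0.0031), the midgut list in replicate 2 alone with 5 of 15 (0.049). With summits counted within the gene or 1000 bp upstream, the ribosomal list passed with 12 of 88 genes above chance and the pan-neuronal list with 1 of 14 below it (adjusted permutation p = 0.020 and 0.046). Of the 77 genes named by the fixed rule, 71 had their strongest peak among the 2824 strongest of replicate 1, and 71 among those of replicate 2. The exceptions in replicate 1 were Vsx1, hth, gcm, futsch, brp and crq, and in replicate 2 numb, Abd-B, Tm1, futsch, E23 and brk.

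**Figure D4:**
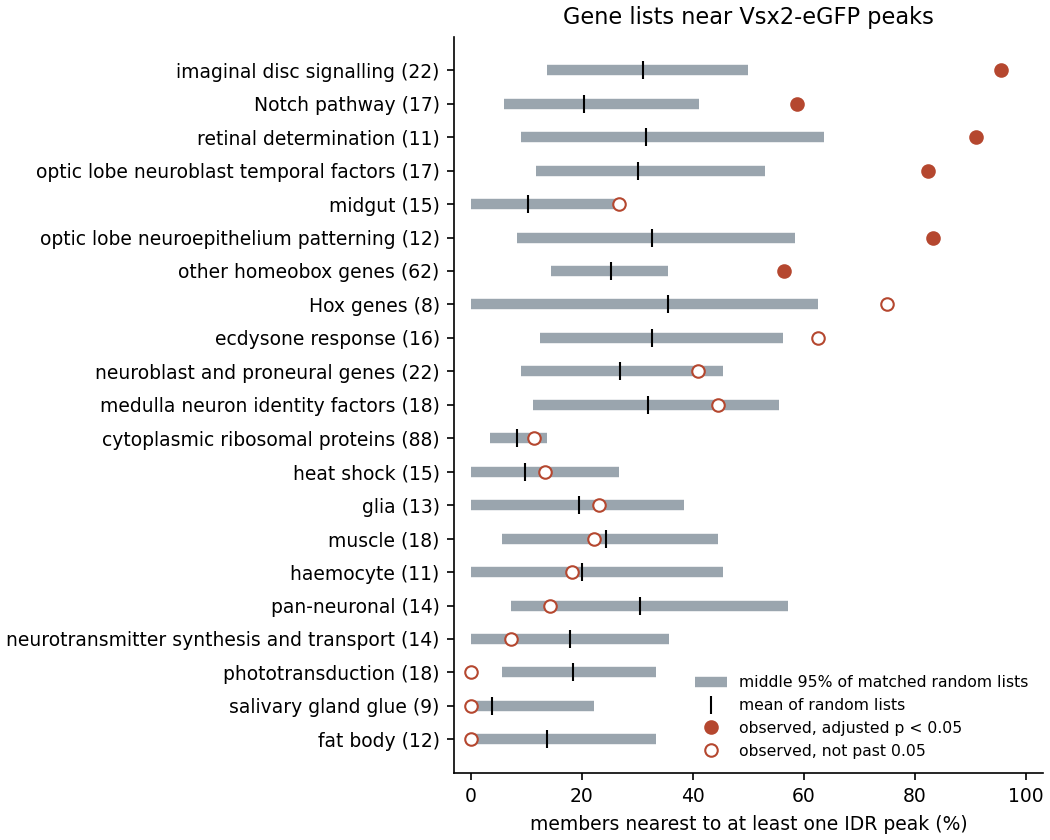
For each gene list, with the number of members in brackets, the circle gives the percent of members nearest to at least 1 IDR peak, filled where the adjusted p was below 0.05. Grey bars and ticks give the middle 95% and the mean of 10000 matched random lists. The 6 filled circles, from 56.5% for other homeobox genes to 95.5% for imaginal disc signalling, lie to the right of their bars.

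Peak summits were enriched over their flanks for the extended homeodomain site TAATTAG but not for the shorter palindrome TAATTA. TAATTAG lay within 100 bp of the summit in 216 of 2824 peaks, or 7.65% (95% Wilson interval 6.73 to 8.69%), against 3.90% in the flanks and 3.97% at the weakest relaxed peaks, a fold of 1.96 over the flanks (permutation p = 1.0e-05, the smallest the resampling can give, adjusted p = 1.5e-05). Its fold was 2.27 in the strongest peaks of replicate 2 and 1.55 in those of replicate 1. TAATTA was found at 12.0% of summits and in 12.4% of flanks (adjusted permutation p = 0.69). It lay above the flanks in replicate 2 alone (15.1% against 12.8%) and below them in replicate 1 alone (9.92% against 11.9%). The other 7 palindromes of A and T were lower at summits than in flanks, from a fold of 0.41 for TTATAA to 0.69 for AAATTT. TAATTA, with a fold of 0.97, lay above each of these controls of the same composition, a difference that was not tested. Every TAATTAG match contains TAATTA, however, and 216 of the 340 peaks with TAATTA had TAATTAG. Summits had TAATTA in 12.0% and TAATTAG in 7.65% of cases, and flanks in 12.4% and 3.90%. TAATTA without TAATTAG was thus less frequent at summits than in flanks, as the controls were, which was not tested either. The summits had a GC content of 47.2% against 42.0% in the flanks.

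GAGA repeats were the most frequent of the motifs tested. GAGAGA, the site of Trithorax-like (GAGA factor), occurred at 30.5% of summits against 9.47% of flanks, a fold of 3.22. Elements of broadly active promoters and of insulators were rarer but had larger folds, with the DRE element TATCGATA at 2.27% against 0.549%, the M1BP element GGTCACACT at 1.52% against 0.195% and the Su(Hw) core TGCATACTT at 1.45% against 0.266%. Zelda-type CAGGTA (6.62% against 4.69%), the E-box CAGCTG (12.1% against 9.01%) and the BEAF-32 site CGATA (24.2% against 21.9%) were also higher, while GATA sites were lower (24.9% against 30.7%). All of these passed the adjusted permutation test, with p from 1.5e-05 to 0.023. CACGTG (2.51% in both) and the AP-1 site (1.63% against 2.05%) did not. Some of these calls depended on the set of peaks or on the window. The DRE and M1BP enrichment was absent from distal peaks, where they occurred at 0.214% and 0.0713% of summits. CAGCTG was also not past the threshold in distal peaks alone (10.2% against 8.95%, adjusted permutation p = 0.25), nor the Su(Hw) core in promoter peaks alone (0.492% against 0.352%, adjusted permutation p = 0.63). CGATA was not past it in replicate 2 alone (adjusted permutation p = 0.052), in the stronger 1412 IDR peaks (0.056) or in distal peaks alone (0.058), where it lay below the flanks. The AP-1 site passed, as lower at summits, in replicate 2 alone (1.45% against 2.09%, adjusted permutation p = 0.039) and within 50 bp of the summit (0.602% against 1.03%, 0.041).

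Among all 6-mers, 185 of 2080 were higher at summits by a fold of at least 1.5 and 271 were lower by as much. The 10 of smallest p were AGAGAG, AGAGCG, GAGAGC, GAGAGA, GAGCGA, GCGAGA, CGAGAG, CTCTCC, AGCGAG and GAGCGC. AGAGAG occurred at 34.5% of summits and 10.1% of flanks (exact McNemar, adjusted p = 2.0e-106), and GAGCGC at 17.9% and 5.70%. Of the 271 lower 6-mers, 121 had at least 5 bases that were A or T. A single higher 6-mer contained TAAT or ATTA, namely ATTAGC, which overlaps the end of TAATTAG. It was found at 18.1% of summits and 11.4% of flanks, and was named after its value was seen.

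TAATTA, and the TAATTAG that contains it, were more frequent in the strongest peaks and in distal peaks. TAATTA was found in 17.9% of the strongest 565 IDR peaks and in 10.6% of the weakest 564 (Fisher's exact test, p = 0.00063), and the 3 parts in between had 11.7%, 10.1% and 9.91%. By location, it was found in 141 of 1422 promoter peaks (9.92%) and 199 of 1402 distal peaks (14.2%), with a Fisher's exact p of 0.00051. In replicate 1 alone the difference was smaller and not past 0.05 (9.14% against 10.9%, Fisher's exact p = 0.13). The same comparisons for TAATTAG, added after its share had been seen, gave 13.1% and 6.56% in the strongest and weakest parts (Fisher's exact p = 0.00029), and 4.99% of promoter against 10.3% of distal peaks (Fisher's exact p = 8.5e-08). The results for the 2 motifs are not independent. Of the peaks with TAATTA, 74 of 101 in the strongest part and 37 of 60 in the weakest had TAATTAG. By location, 71 of 141 promoter and 145 of 199 distal peaks with TAATTA did. TAATTA without TAATTAG thus differed little by strength and was not more frequent in distal peaks, which was not tested. Against their own flanks, distal peaks had TAATTAG 2.66 times as often (adjusted permutation p = 1.9e-05), and promoter peaks 1.28 times as often (adjusted permutation p = 0.15).

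**Figure D5:**
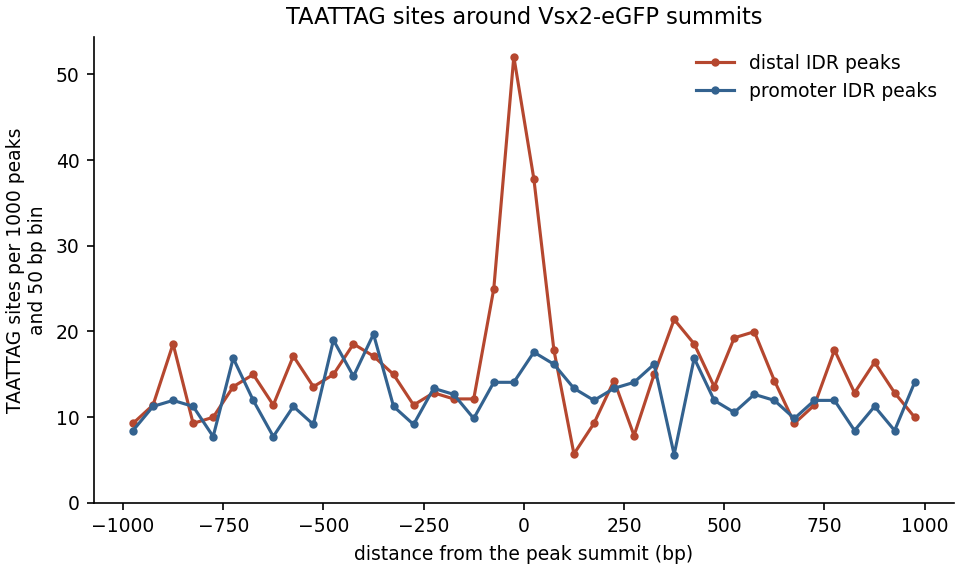
TAATTAG sites on either strand per 1000 IDR peaks in bins of 50 bp (vertical axis), by distance from the summit in bp (horizontal axis), for 1402 distal and 1422 promoter peaks. Distal peaks rise to 52.1 sites per 1000 peaks in the bin next to the summit, and promoter peaks stay between 5.63 and 19.7 over the whole window. Sites are counted rather than peaks, and a sequence that matches on both strands may count more than once.

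Fewer peaks per Mb lay on X than on the large autosomal arms. Larvae of both sexes were pooled, so X had fewer copies than the autosomes. How far this lowers the number of peaks on X was not tested. X had 331 IDR peaks, or 14.1 per Mb, and arms 2L, 2R, 3L and 3R together had 2477, or 22.7 per Mb, a ratio of 0.619 (95% Wilson interval 0.552 to 0.694). The weakest relaxed peaks gave a lower ratio, 0.514, and the difference between the sets had a Fisher's exact p of 0.032. That difference was not past 0.05 in replicate 2 alone (ratio 0.547, Fisher's exact p = 0.43) or in the dm3 lists (0.563 against 0.572, Fisher's exact p = 0.90). Chromosome 4 held 16 IDR peaks, and Y held no peak in the lists on dm6.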

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

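In the dm3 IDR list, 8 peaks lay on sequences outside the main arms, which is above the fixed limit of 3 used to flag data left out. No expected number was worked out, so an excess is not shown. The unplaced collection Uextra held 6 of them, and 2RHet and 3LHet held 1 each. The strongest had a signal value of 427.4 and rank 105 in that list. No comparison used these peaks.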

How the results depend on the processing

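The replacement of TAATTA by TAATTAG, the omission of the strongest 282 peaks and the split of TAATTAG positions by location were chosen after the results had been seen, and the other alternatives before. Replicate overlap (40.5 to 56.2%), promoter share (42.9 to 60.4%) and the promoter excess in signal kept their direction and their call in each alternative run. So did the excess of TAATTA in the strongest part of the peaks over the weakest part. It was not a steady trend, since in replicate 2 alone the share was 21.8% in the strongest part, 9.56% in the next and 15.4% in the weakest. The count of enriched 6-mers (146 to 236) stayed within 1.5 times its main value. Among the alternatives for the main results, 70 gave the same call and 8 did not. With single replicates, the ratio of X to autosomal density ran from 0.547 to 0.690, the TAATTA share at summits from 9.92 to 15.1%, and the promoter minus distal difference in TAATTA from -5.16 to -1.73 points. The density call was lost without replicate 1, the TAATTA share lay below its flanks without replicate 2 and above them without replicate 1, and the location difference was not past 0.05 without replicate 2. In the dm3 lists the density ratio, 0.563, fell below that of the background peaks. With flanks 500 bp away, TAATTA at 12.0% was lower than its flanks past the threshold. With promoter peaks alone, TAATTAG at 4.99% was no longer past it. With the stronger 1412 IDR peaks, 3 gene lists passed in place of 6. With distal peaks alone, TATCGATA (0.214%), GGTCACACT (0.0713%) and CGATA (19.0%) lay below their flanks, each not past the threshold. For these changes the cause was not tested. Of the alternatives for single lists, motifs and named genes, 476 gave the same outcome and 34 did not. Replicate overlap and correlation could not be run with a replicate left out, nor X density without X. No paired analysis was possible because there was a single group. Sequencing depth was not analysed here, so whether it limits the weaker peaks is open.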

Other observations

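Of the tests here, the comparison of optic lobe with disc genes, the genes with the most peaks, the 6-mers of strong promoters, the motif shares of strong distal peaks and the placement of TAATTAG by location were chosen after the results had been seen. The genes with the most IDR peaks were Eip75B and shn with 12 each, followed by InR, Tlk and mam with 9 each. Eip75B is a nuclear receptor gene induced by ecdysone, shn encodes a zinc finger factor of Dpp signalling, InR is the insulin receptor gene and mam encodes a Notch coactivator. The searched distance around each of these was long, from 46.3 kb at InR to 112.2 kb at Eip75B. Pooled over 3 lists, genes of the optic lobe were occupied less often than those of the disc list. Of 41 genes in the 3 optic lobe lists and not in the disc list, 26 had a peak (63.4%), against 16 of 17 genes of the disc list alone (94.1%, two-sided Fisher's exact p = 0.023). The 5 genes in both had a peak each. Among the whole lists, medulla neuron identity factors had the low share (8 of 18, 44.4%), while neuroepithelium patterning (83.3%) and temporal factor genes (82.4%) were closer to the 95.5% of the disc list.

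TAATTAG at summits, of distal peaks above all, may mark direct contact of Vsx2-eGFP with DNA through its homeodomain. The base composition of summits is argued against as the source, since TAATTAG had the highest fold of 448 7-mers with 1 G or C and 6 A or T. Its percentile among them was 100, and its fold of 1.96 lay beyond the 0.966 that bounds the middle 95%. Copies of a repeat are argued against by a fold of 2.44 among the 682 peaks without a soft-masked base near the summit. Over all peaks the site was 1.65 times as frequent per bp within 25 bp of the summit as 50 to 97 bp away (two-sided exact binomial p = 0.00082). In distal peaks the ratio was 1.95 (95% interval 1.34 to 2.82, exact binomial p = 0.00027). In the 1422 promoter peaks it was 1.19 (0.682 to 2.03, exact binomial p = 0.51), so a placement at the summit was not shown there. These tests treat sites as independent. Sites were counted rather than peaks, however, and some peaks held several sites. A sequence that matches on both strands may count more than once. The p-values and intervals may thus overstate the evidence for a placement at the summit. Other homeodomain proteins recognise similar sites, and peaks of other factors were not analysed here, so which protein reads the site stays open.

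The strongest 282 peaks lay at promoters in 199 cases (70.6%), and open promoter chromatin and sequence-specific binding are both candidate explanations. Repeats masked in the assembly are argued against as the source of most of these peaks, since 0.503% of the 199 were mostly soft-masked. The share among the weaker IDR peaks was 1.38%, a difference not past 0.05 (Fisher's exact p = 0.51). Repeat copies missing from the assembly would not be seen this way. TAATTAG was 2.32 times as frequent at the 199 peaks as in their flanks and more frequent than at weaker promoter peaks (11.1% against 4.01%, Fisher's exact p = 0.00014), yet it was absent from most of them. DRE or M1BP elements were found at 13.1% of the 199 peaks and 5.89% of weaker promoter peaks (Fisher's exact p = 0.00071), which leaves a contribution of core promoter elements of broadly active genes open. None of the 20 strongest peaks had either element, however, and 1 of the 20 had GAGAGA, against 35.5% of the 282. Both sequence explanations thus cover a minority of the peaks, and enrichment at open promoters regardless of the tagged factor was not tested, since ChIP of other or untagged lines was not analysed here.

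TAATTAG was most frequent, among the 4 sets of strong or weaker and distal or promoter peaks, in strong distal peaks. Of the 83 distal peaks among the strongest 282, 24 contained TAATTAG (28.9%, 95% Wilson interval 20.3 to 39.4%), and their flanks did so in 1.81% of cases. Among the 1319 weaker distal peaks the share was 9.17%, with 4.02% in the flanks. Whether strength matters more in distal than in promoter peaks was not tested. Of 2080 6-mers compared between the strongest and the weaker promoter peaks, 5 passed an adjusted p of 0.05 by Fisher's exact test, and all 5 were higher in the strongest. CCGATA led them with 18.1% against 6.05%. ATTAGC, which overlaps the end of TAATTAG and adds a C, was at 22.6% against 11.3%. TAATTAG itself was at 11.1% of the strongest promoter peaks, so it cannot account for all ATTAGC matches there.

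The peaks at Vsx2 may reflect binding at the gene's own control regions or extra copies of the tagged locus in the transgenic line. Within Vsx2 and 20 kb to each side, 7 IDR peaks were found, more than in 98.5% of 4565 windows of the same length on X, where the median was 0. Of these 7, 4 were assigned to Vsx2, 1 to Vsx1 and 2 to CG12730. Without the peaks of CG12730, the count would lie below the 6 that bound the middle 95% of windows. The relaxed peaks outside the IDR list numbered 7, equal to the median of 7 in those windows and below the 22 that bound the middle 95%. A raised number of such peaks was thus not seen in the pooled list, but extra copies cannot be told apart from binding. IDR peaks were left out of this count, and the lists of single replicates were not compared with windows. In replicate 1, Vsx2 held a peak at 5545881 (rank 1612) without a counterpart within 100 bp in the pooled list. Replicate 2 had such peaks at 5551010 and 5556043 (ranks 2076 and 2134). A control library carrying the same copies would cancel a raised background. Whether the control came from the same line is not stated in the labels.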
